A study of Saccharomyces cerevisiae with 4 samples.

How the data were processed

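Total RNA of Saccharomyces cerevisiae BY4741, a haploid laboratory strain that is the wild type of the study, was compared on 4 spotted 2-colour DNA arrays. Per the labels, each array carried cDNA of a culture exposed to caspofungin at 15 ng/ml and cDNA of the untreated part of a culture, both grown at 24 °C. Caspofungin is an echinocandin antifungal drug that inhibits the synthesis of β-1,3-glucan in the cell wall. Per the series' design text, RNA of 2 cultures was used and each was hybridised with both dye orientations. The treated RNA carried Cy3 on arrays 1 and 3 and Cy5 on arrays 2 and 4. The labels do not say which arrays share a culture. All 4 titles give an exposure of 2 h, but the treated channel of array 4 is labelled 3 h. The array was kept, and values without it were computed.

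The only values used were the log2 ratios deposited by the authors, with 1 column per array. The scanner, background correction, spot filter and normalization behind them are not given in the sources used here. The log base was found from the values. Raising 2 to the power of each value gave a number of 4 decimals in 100% of the 17068 filled cells, within 0.05 of the fourth decimal, against 10.2% for base e and 10.1% for base 10. The table held 6209 spots, of which 2 control spots were left out. Of the 6207 gene spots, 5654 matched a locus tag of the RefSeq table of assembly R64 and 553 did not and kept their deposited names. That table was used for names only. Each name had 1 spot. Values were present on all 4 arrays for 3740 genes, on 3 arrays for 369, on 2 for 303, on 1 for 387 and on 0 for 1408. Arrays 1 to 4 held values for 4399, 4042, 4101 and 4518 genes, and their medians as deposited were -0.131, -0.118, -0.11 and -0.0969, so the arrays had not been centred on the median. No intensities were used here, so no filter on dim spots could be set, and the number of arrays limits the precision.

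The direction of the ratios was not stated. The design fixed before the data were examined had assumed ratios of fixed dyes, to be turned by the dye labels. The values did not behave as such ratios. Arrays of opposite orientation correlated weakly above 0 across genes, with Pearson's r from 0.146 to 0.216, where dye ratios would oppose each other. Spearman's rho lay between -0.027 and 0.115, so the relation rested on genes with large ratios. Turning them by the dyes left 0 genes past the threshold instead of 184, and 16 genes instead of 60 at 2-fold or more with one sign on all 4 arrays. The ratios were therefore taken as already turned to one direction by the authors and were used without turning, which departs from the planned design. Caspofungin over untreated is the likely direction, because the titles name the exposure and the description speaks of treated against non-treated samples. No label settles it, and if the deposited ratios ran the other way every sign given here would turn. Scale and direction thus rest on the values and the titles, and the authors' normalization stays unknown.

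Each array was centred on the median of all genes with a value on it, and the 3740 genes with a value on all 4 arrays were tested. The arrays of a culture were averaged, and the 2 culture means were tested against 0 with limma's moderated test (lmFit and eBayes, two-sided; limma 3.58.1, R 4.3.3). Because the pairing of arrays was unknown, both pairings that the dyes allow were fitted (arrays 1 with 2 and 3 with 4, or 1 with 4 and 2 with 3). A gene took the larger p and the larger SE of both, and p-values were adjusted by the Benjamini-Hochberg method and called at 0.05. The prior degrees of freedom were 4.74 and 2.93, against 1 residual degree of freedom. Means are over 4 arrays, and each SE is the moderated SE of 2 culture means. It is not the SD among arrays, which also holds the difference between orientations. A dye-orientation effect was tested with limma on the 4 arrays with an orientation term. Gene lists were tested with camera (two-sided, preset inter-gene correlation 0.01) on the culture means, again taking the larger p of both pairings and adjusting over the 31 lists, and with an estimated correlation beside it. Camera compares a list with all other genes.

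The 31 gene lists and the rule for named genes were fixed before the data were examined. The rule took the 15 largest rises and the 15 largest falls among genes past the threshold, changed at least 2-fold and with one sign on all 4 arrays. It took up to 4 members of each list past the threshold with the largest change, or up to 2 members where none passed. FKS1, GSC2 (FKS2), SLT2, CHS3 and the marker genes deleted in the strain (HIS3, LEU2, MET17 and URA3) were to be given where measured. No fall met the 2-fold rule, and 1 gene that the rule names is not reported here. The alternatives covered centring, scale and quantile normalization, missing values, the pairing, the unit of replication, each orientation alone, variance shrinkage, thresholds, the set test and each array left out in turn. Figures were drawn with matplotlib 3.10.9.

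The test was tried on simulated data of 3740 genes with 200 changed genes, in 20 simulations under each of 2 noise models. Both took their variances from the fit of 4 arrays with an orientation term, not from the culture means that were tested. Noise was put on arrays and on cultures in equal parts, with arrays 1 and 2 in one culture. With variances drawn from the prior fitted there, whose form the test assumes, changes of 0.5, 1, 2 and 3 on the log2 scale were recovered in 11.0%, 89.1%, 98.7% and 99.7% of cases, and 4.3% of the calls were unchanged genes. With each gene's own moderated variance, recovery was 71.0%, 99.6%, 100% and 100%, but 11.0% of the calls were unchanged genes, above the nominal 5%. With no changed gene, the mean number of calls was 0.1 under the first model and 4 under the second, where it reached 24 in 1 simulation. A list shifted by 0.5, the cell wall integrity output list, was called in 100% of simulations under both, and a mean of 1.1 and 0.9 other lists were called with it. Of these, a mean of 0.15 and 0 lists shared no gene with the shifted list, so lists that share genes are not separate findings. Genes were simulated as independent of each other. The share of false calls among the genes reported may thus exceed the threshold.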

Results

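Log2 ratios of 4 arrays were analysed, which compared RNA of wild-type yeast exposed to caspofungin with RNA of untreated cells. They came from 2 cultures, each measured in both dye orientations, so n is 2 cultures for the tests of caspofungin against untreated. The comparison asks which transcripts changed within the first hours of inhibition of glucan synthesis. Values are log2 ratios of caspofungin over untreated, which is the likely direction of the deposited table but not a settled one, since no label states it. They are given relative to the median gene of each array.

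Of the genes regulated by the cell wall integrity pathway and measured on all 4 arrays, 15 of 17 rose. So did 11 of 25 genes of cell wall mannoproteins and yapsins and 11 of 28 genes of the induced stress response. Most mannoprotein genes that rose also belong to the integrity list, and SPI1 also to the stress list, so these counts are not separate findings. Each of these lists passed the set test with its preset correlation but not with an estimated one (adjusted p = 0.926 for each with an estimated correlation). On 2 culture means that estimate leaves 1 residual degree of freedom, and 0.926 was the smallest adjusted p over all 31 lists. With so little power, it cannot decide for or against a list, here or below. Of 3740 genes tested, 153 were higher and 31 were lower at adjusted p under 0.05 (limma). The median size was 1.79-fold among the genes called higher and 1.55-fold among the genes called lower. At least 2-fold and with one sign on all 4 arrays, 60 genes were higher and 0 were lower. At an unadjusted p under 0.05, 626 genes were higher and 426 lower. Without centring of the arrays the calls were 60 higher and 23 lower, so that 72.3% of the calls were higher instead of 83.2%. The number of calls moved by over 1.5 times when any of the arrays was left out, with 78, 61, 43 and 120 calls without arrays 1, 2, 3 and 4. In each of these fits 1 culture rests on a lone array, so the orientation effect does not cancel there and can itself end calls. A core of 36 genes was called in all 4 of these fits, and all 36 were higher. Of the 51 genes past the threshold that the rule for named genes gave, 18 were in this core and 14 were called in none of the 4 fits, among them 7 of the 8 falls.

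The highest named ratio was that of YFL013W-A, at 4.89 ± 0.19 (SE, n = 2 cultures; adjusted p = 0.0141). This name is not in the RefSeq table and lies beside that of HSP12 in the numbering of the chromosome, so its probe could have bound transcripts of a neighbour and the value is uncertain. HSP12 (YFL014W), which encodes a small membrane-associated stress protein, was higher by 3.50 ± 0.24 (adjusted p = 0.0142), and its 4 arrays ranged from 2.47 to 5.15. CRG1 (YHR209W), which encodes a methyltransferase involved in resistance to cantharidin, was higher by 2.93 ± 0.09 (adjusted p = 0.0115) and lay between 2.84 and 2.99 on the 4 arrays. CWP1 (YKL096W), a mannoprotein of the cell wall, was higher by 2.78 ± 0.10 and differed between orientations (adjusted p = 0.0366), with 2.21 and 2.34 where the treated RNA carried Cy3 and 3.51 and 3.08 where it carried Cy5. RTC3 (YHR087W), a stress-induced gene, was higher by 2.67 ± 0.27. NCW2 (YLR194C), another cell wall protein gene, followed at 2.55 ± 0.12. All of these kept their call with each array left out in turn. Further down were PRM5 at 2.32, the wall protein gene SED1 at 2.11, SRL3 at 2.09, YPL088W at 1.96, KDX1 at 1.85 and PST1 at 1.82. The last of the 15 largest rises were YEL074W at 1.81, PIR5 at 1.77 and NQM1 at 1.72. YEL074W is not in the RefSeq table either. PIR5 differed between orientations (adjusted p = 0.0258), with 2.50 and 3.02 where the treated RNA carried Cy3 and 1.10 and 0.46 where it carried Cy5.

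**Figure D1:**
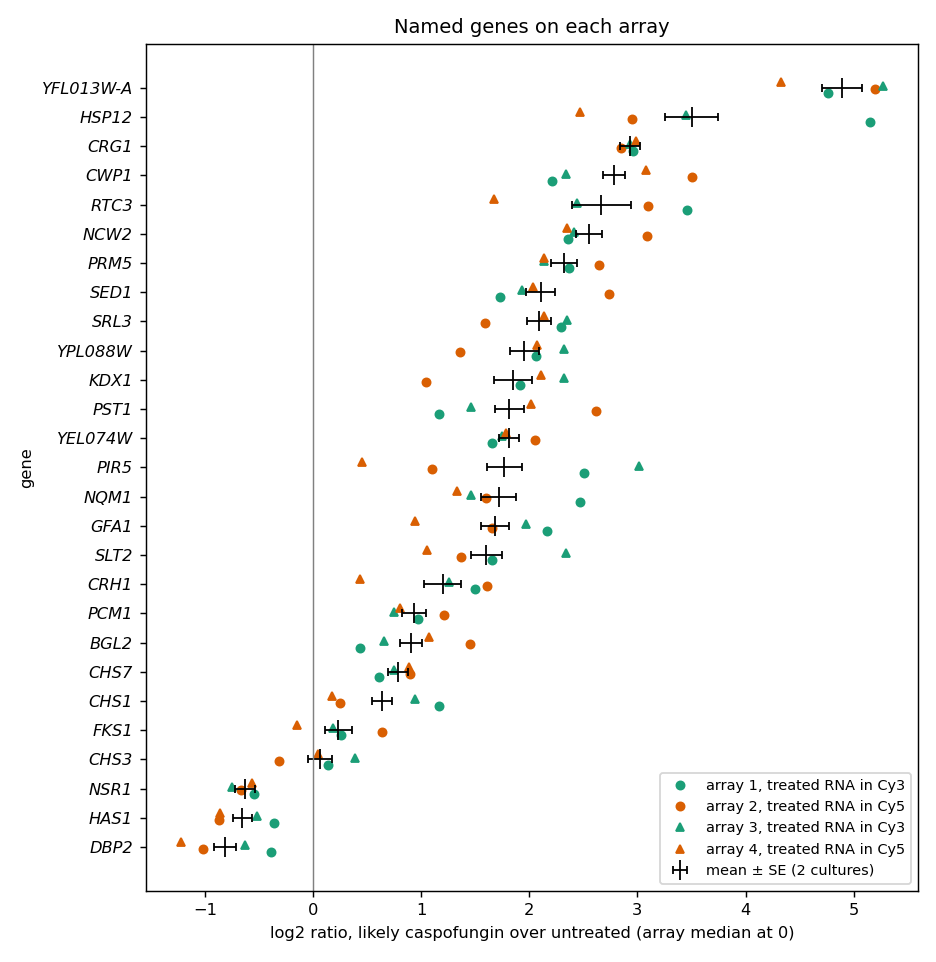
Log2 ratios of named genes, likely caspofungin over untreated and relative to each array's median (horizontal axis), for each gene (vertical axis). Points are the 4 arrays, coloured by the dye of the treated RNA, and black marks are the mean ± SE of 2 cultures. The 15 largest rises lie above 0 on every array, while FKS1 and CHS3 lie on both sides of 0. The rises were chosen for one sign on all 4 arrays and FKS1 and CHS3 were not, so this contrast follows from the choice.

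Genes regulated by the cell wall integrity pathway, the kinase cascade that ends in Slt2 and the transcription factor Rlm1, rose together. Of the 17 members measured on all 4 arrays, 15 rose, 0 fell and 2 did not pass. Adjusted over the list alone, 16 rose. Their median was 1.39, and the medians on arrays 1 to 4 were 1.28, 1.55, 1.44 and 1.27. CWP1, NCW2, PRM5 and SED1 led the list, and CIS3 (0.90) and CHS3 (0.07) did not pass. PTP2, YPS1, GSC2 and RLM1 of the list had values on 3 arrays only and are not counted here. Their means over both orientations were 0.76, 0.31, 0.29 and 0.16, and YPS1 and GSC2 had signs that differed among arrays. The list stood above other genes in camera (adjusted p = 9.14e-12, but adjusted p = 0.926 with an estimated correlation). Of the 14 measured components of the pathway itself, 5 rose and 0 fell, or 6 and 0 adjusted over the list alone (camera adjusted p = 0.0465; adjusted p = 0.926 with an estimated correlation). These were KDX1, which encodes a pseudokinase paralog of Slt2, SLT2 at 1.60 ± 0.15 (adjusted p = 0.0312), the Rho1 GTPase-activating protein gene LRG1 at 1.34, the phosphatase gene MSG5 at 0.52 and RHO1 at 0.51. Of these, KDX1 and SLT2 are also counted in the output list. PKC1 at 0.03 and BCK1 at 0.11 did not pass.

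Among 25 mannoproteins and yapsins of the cell wall, 11 rose and 0 fell, or 15 and 1 adjusted over the list alone, with a median of 0.47, or 0.282 and 0.285 on arrays 1 and 3 and 0.743 and 0.56 on arrays 2 and 4 (camera adjusted p = 0.00222; adjusted p = 0.926 with an estimated correlation). They were CWP1, NCW2, SED1, PST1 and PIR5 with PIR3, HSP150, PIR1, SPI1, YPS3 and FLO9, and the PIR genes among them are similar in sequence, so their probes may share signal. All but PIR5, SPI1 and FLO9 are also in the list of integrity output genes, so the lists are not separate findings. CCW12 at 0.47 and ECM33 at 0.07 did not pass. The 21 genes of glucan synthesis and remodelling did not move as a list (camera adjusted p = 0.436), with a median of 0.10. In it 3 rose and 1 fell, or 4 and 1 adjusted over the list alone. The transglycosylase gene CRH1 rose by 1.20 ± 0.17 (adjusted p = 0.0397), BGL2 by 0.90 and ROT1 by 0.54, and GAS3 fell by 0.56. The fall of GAS3 was 0.36 without array 3, and it was not called with any array left out. FKS1, which encodes the main catalytic subunit of the glucan synthase that caspofungin inhibits, had 0.23 ± 0.13 (adjusted p = 0.276). GSC2, the gene of the alternative subunit Fks2, had values on 3 arrays only, at -0.93, 1.39 and -0.71. It was tested only among genes with values on at least 3 arrays, where it had -0.26 ± 0.30 (adjusted p = 0.608). Its mean over both orientations was 0.29, so no direction can be given.

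In chitin synthesis, 4 of 14 measured genes rose and 0 fell, or 6 and 0 adjusted over the list alone, and the list did not pass (median 0.18, camera adjusted p = 0.0722). The genes were GFA1, which encodes the first enzyme of the hexosamine pathway, at 1.68 ± 0.13 (adjusted p = 0.019), PCM1 of the same pathway at 0.93, CHS7, needed for export of the chitin synthase Chs3, at 0.78, and CHS1 at 0.63, which differed between orientations (adjusted p = 0.036), had 0.40 without array 1 and lost its call without array 1, 2 or 3. CHS3 itself had 0.07 ± 0.11 (adjusted p = 0.725). Of 14 daughter cell separation genes, 3 rose and 0 fell, or 4 and 0 adjusted over the list alone, with a median of 0.23 (camera adjusted p = 0.00768; adjusted p = 0.926 with an estimated correlation). They were the wall genes PIR1 at 1.01 and CHS1, which other lists hold too, and DSE2 at 0.77. None of the 32 measured genes of protein mannosylation and glycosylation passed; PMT6 had 0.76 and PMT3 0.55, and the list's median of -0.05, mean of 0.02 and camera direction (lower, adjusted p = 0.613) differed in sign.

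Of 28 genes of the induced environmental stress response, 11 rose and 0 fell, or 18 and 1 adjusted over the list alone, and the median was 0.55 (camera adjusted p = 2.16e-08; adjusted p = 0.926 with an estimated correlation). HSP12, RTC3, NQM1 and TFS1 (1.37 ± 0.19) led it. HSP12, RTC3 and NQM1 also led the list of osmotic stress and HOG pathway targets with HOR7 at 1.22, and in that list 5 of 14 rose and 1 fell, or 7 and 1 adjusted over the list alone (median 0.29, camera adjusted p = 0.014; adjusted p = 0.926 with an estimated correlation). The gene that fell was the hexose transporter gene HXT1, by 0.59. Trehalose and glycogen metabolism had 2 rises and 0 falls among 13 genes, or 4 and 0 adjusted over the list alone, with a median of 0.16 (camera adjusted p = 0.0465; adjusted p = 0.926 with an estimated correlation). They were the glycogen synthase gene GSY2 at 1.13 and the branching enzyme gene GLC3 at 0.57, and the list lost its call without array 1, 2 or 3, with adjusted p = 0.198, 0.0607 and 0.1. Of 11 calcineurin and Crz1 targets, 4 rose and 0 fell, or 5 and 0 adjusted over the list alone (median 0.51, camera adjusted p = 0.0197; adjusted p = 0.926 with an estimated correlation). They were CRH1, the calmodulin-dependent kinase gene CMK2 at 0.87, RCN2 at 0.84 and CHS1. The list's medians were 1.16 and 0.685 on arrays 1 and 3 and 0.254 and 0.234 on arrays 2 and 4, and it lost its call without array 1 (adjusted p = 0.0665). None of 26 heat shock chaperone genes passed (HSP26 0.47, HSP10 0.45), and that list lay above 0 on arrays 1 and 3, with medians of 0.24 and 0.30, and below 0 on arrays 2 and 4, with -0.15 and -0.36.

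Of 45 genes of the TCA cycle and respiration, 4 rose and 0 fell, or 12 and 1 adjusted over the list alone, with a median of 0.26 (camera adjusted p = 4.25e-06; adjusted p = 0.926 with an estimated correlation). They were the citrate synthase genes CIT1 at 0.93 and CIT2 at 0.51, KGD1 of the α-ketoglutarate dehydrogenase at 0.87 and QCR7 of the cytochrome bc complex at 0.53. CIT2 acts in peroxisomes, outside the TCA cycle. The only list lower than other genes was ribosome biogenesis. Of its 74 measured genes, 5 fell and 0 rose, or 26 and 3 adjusted over the list alone, with a median of -0.25 (camera adjusted p = 1.14e-06; adjusted p = 0.926 with an estimated correlation). The helicase gene DBP2 fell by 0.81 ± 0.10 (adjusted p = 0.0307), HAS1 by 0.65, the nucleolin-like gene NSR1 by 0.63 and SOF1 by 0.56, and RLP24 by 0.55, with values below 0 on all 4 arrays for the first 4. Among these 74 genes, which had values on all 4 arrays, the shift came from arrays 2 and 4. The list's medians were -0.44 and -0.40 there, against 0.01 and -0.03 on arrays 1 and 3. On arrays 1 and 3 alone the list was not called (camera adjusted p = 0.704). Partly blank members of the list are not counted here, and several of them were below 0 on array 1 or 3 as well. The 130 cytosolic ribosomal protein genes had a median of 0.02, with 0 rises and 0 falls (camera direction lower, adjusted p = 0.958); RPL41A had 0.29 and RPL15B -0.27, with signs that differed among arrays. RPL41A differed between orientations (adjusted p = 0.0478), with 0.95 and 1.00 on arrays 1 and 3 and -0.84 and 0.05 on arrays 2 and 4, and RPL15B ranged from -1.76 to 0.65.

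**Figure D2:**
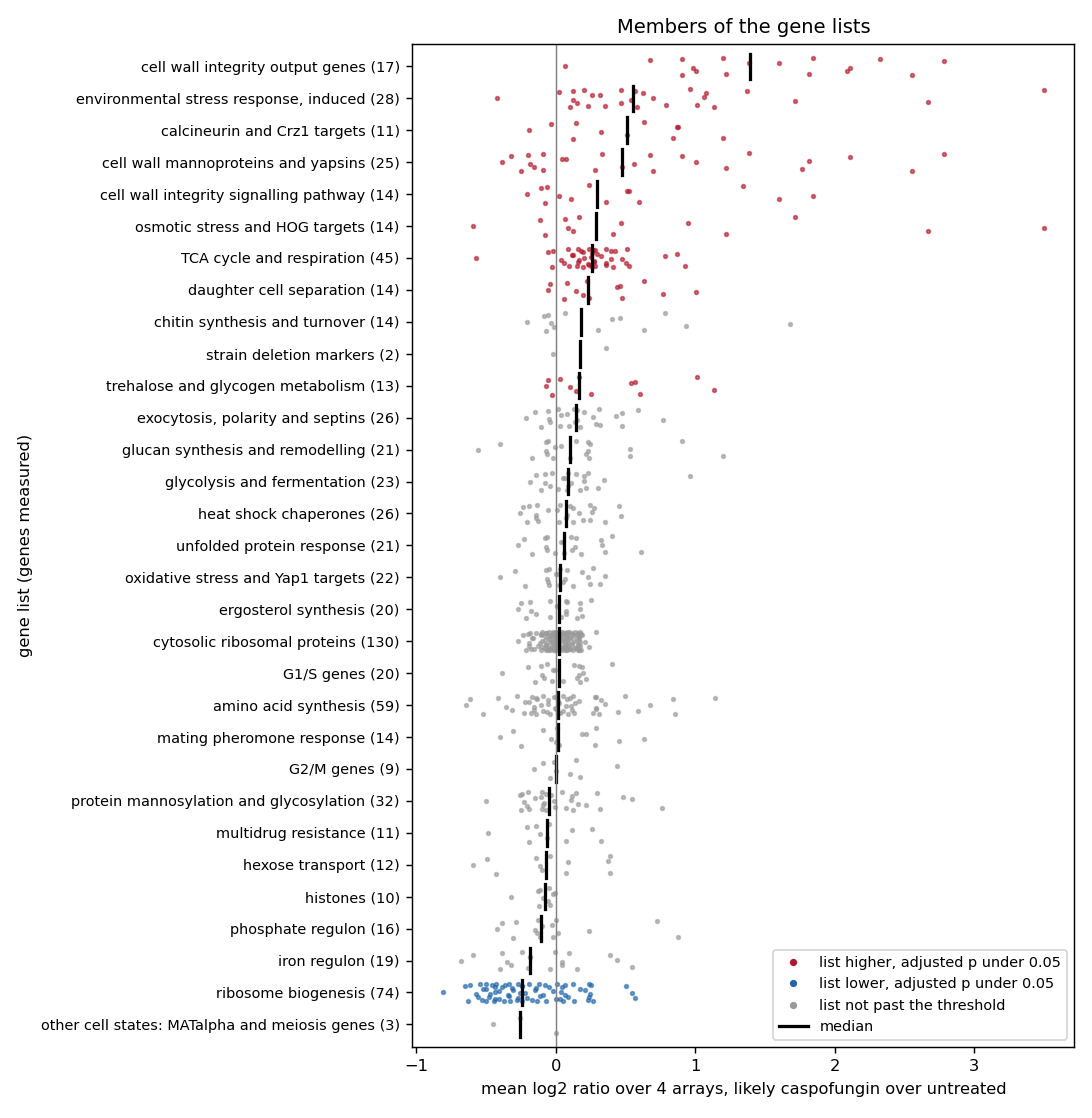
Mean log2 ratio over 4 arrays (horizontal axis) of each measured member of the 31 gene lists (vertical axis, genes measured in brackets), coloured by camera's call with the preset correlation, with the list median as a black bar. The cell wall integrity output list has the highest median, 1.39, and ribosome biogenesis is the only list called lower, with a median of -0.25.

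In the other lists few genes passed. Glycolysis and fermentation had 1 rise among 23 genes, GLK1 at 0.96, amino acid synthesis 3 rises and 1 fall among 59 (ARO9 0.86, MET6 0.84 and SER3 0.59, with ILV2 lower by 0.64), and the phosphate regulon 1 rise among 16, PHM8 at 0.72. The iron regulon had 1 fall among 19 genes, the reductase gene FRE1, which fell by 0.68, and hexose transport 1 fall among 12, HXT1. Exocytosis, polarity and septins had 1 rise among 26, the calmodulin gene CMD1 at 0.59 (camera adjusted p = 0.0722), and the mating pheromone response 1 among 14, CHS1. Adjusted over the list alone, the rises and falls were 1 and 0 in glycolysis, 7 and 5 in amino acid synthesis, 2 and 0 in the phosphate regulon, 1 and 1 in the iron regulon, 1 and 2 in hexose transport, 4 and 0 in polarity and 2 and 0 in the pheromone response. No gene passed among 21 of the unfolded protein response (PDI1 0.61, INO1 0.40), 20 of G1/S (GIC1 -0.39), 9 of G2/M (YRB2 0.44, SPO12 0.18), 10 histones (HTA1 -0.32, HHF2 -0.13), 20 of ergosterol synthesis (CYB5 -0.27, ERG20 0.25), 22 of oxidative stress (GPX2 -0.40, TRX1 0.36) and 11 of multidrug resistance (TPO1 -0.48, QDR2 0.33). None of these lists passed camera, and ergosterol synthesis had a median of 0.02 with a mean and a camera direction below 0. Of genes of another mating type and of meiosis, 3 were measured and 0 passed, or 0 rose and 2 fell adjusted over the list alone; MF(ALPHA)2 had -0.45 and SMK1 -0.25. Both differed between orientations (adjusted p = 0.019 and 0.0371), with MF(ALPHA)2 at -1.22 and -1.23 on arrays 1 and 3 and 0.34 and 0.32 on arrays 2 and 4, and SMK1 at -0.62 and -0.64 against 0.06 and 0.19. Of the markers deleted in the strain, HIS3 had 0.36 ± 0.11 (adjusted p = 0.102; past the threshold adjusted over the list alone) and LEU2 -0.02 ± 0.09 (adjusted p = 0.915), although both genes carry deletions in the strain. MET17 had a value on 1 array and URA3 on 0.

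Values differed between arrays of opposite dye orientation, whether through the dye or through a batch that followed it. Across genes, which are not independent replicates, arrays of one orientation correlated at r = 0.778 (arrays 1 and 3) and 0.615 (arrays 2 and 4), and arrays of opposite orientation at 0.146 to 0.216. Spearman's rho was 0.772 and 0.548 within an orientation and -0.027 to 0.115 between orientations. A difference between orientations was found for 443 genes at adjusted p under 0.05 (limma), of which 228 were higher and 215 lower where the treated RNA carried Cy5. Of the 184 genes called for caspofungin, 26 were among them. Genes named above that also differed were YPS3, with 0.03 and 0.35 on arrays 1 and 3 and 0.96 and 1.36 on arrays 2 and 4, CCW12, with 0.05 and 0.19 against 0.86 and 0.79, and GIC1, with -0.82 and -0.93 against 0.21 and -0.02. Of the 3740 genes, 27.5% had one sign on all 4 arrays, against 27.6% for orientations unrelated to each other, given how often the arrays of each orientation shared a sign, so the share over all genes was no larger than that. Among the genes called, 150 of the 153 higher and 29 of the 31 lower ones had one sign on all 4 arrays. Calling picks genes whose culture means agree and lie far from 0, so this follows in part from the calling and is no separate support.

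**Figure D3:**
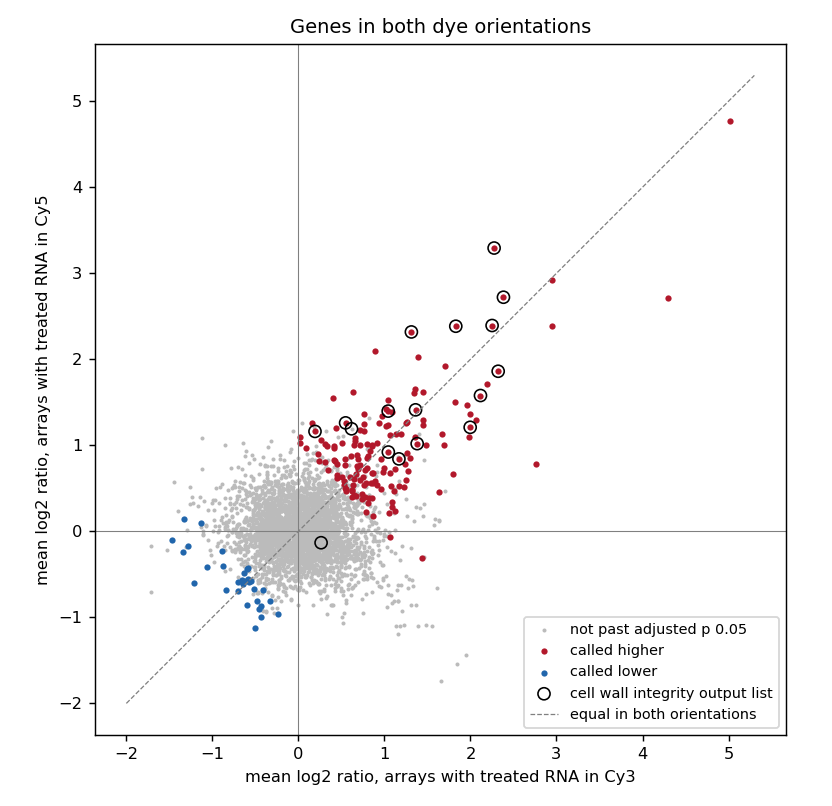
Mean log2 ratio of each of 3740 genes on the arrays with treated RNA in Cy3 (horizontal axis) and in Cy5 (vertical axis), with called genes coloured, the cell wall integrity output list ringed and a dashed line where both are equal. The genes not called spread without a clear relation between orientations. Of the 153 genes called higher, 150 have one sign on all 4 arrays, which follows in part from the calling.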

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

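In 5 of 93 sets of 4 array values, 1 array lay far from the other 3. Chance gives about 1 in 20 for 4 unrelated arrays, but arrays of one orientation resembled each other here and the sets share genes, so the rate expected for these sets is not known. The tests on the low values of array 1 were chosen after those values had been seen. NCW2 was at 3.09 on array 2 and between 2.35 and 2.41 on the others. HOR7 was at 0.674 on array 3 and between 1.36 and 1.47 on the others. RCN2 was at 1.29 on array 1 and between 0.658 and 0.727 on the others. The iron regulon had a median of -0.255 on array 3 and between 0.0467 and 0.0685 on the others. The highest value of array 4 was 4.33, against 5.15 to 5.28 on the others. Array 4 is the one labelled 3 h in its treated channel; the median of the genes called higher was 0.801 on it and 0.886, 0.955 and 0.852 on arrays 1 to 3, and no test set the labelled times apart.

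Array 1 held 19 values below -2, against 3, 4 and 0 on arrays 2, 3 and 4, with GUD1 at -7.70 and SSY1 at -5.52, both blank on the other arrays. A lower RNA level in the culture of array 1 would place the same genes low on its partner of opposite orientation, array 2 or array 4. Their median was -0.229 on array 4 (SE 0.13, 10 genes with a value) and -0.17 on array 2 (SE 0.249, 5 genes), which argues against it for the genes with a value there. The other 9 genes on array 4 and 14 on array 2, among them GUD1 and SSY1, were blank, and for them it stays open. A dye effect of the orientation would place them low on array 3, where their median was -0.22 (SE 0.173, 7 genes), which argues against that for these 7, and for the 12 genes blank there it stays open. A fault of single spots on array 1 was not tested and stays open, so low values seen on that array, such as SKN1 at -3.40, carry no call here.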

How the results depend on the processing

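All counts here are limma calls, to set against 184 (153 higher, 31 lower) unless said otherwise, and the alternatives chosen after seeing the data are the estimated correlation on 4 arrays, the share of rises in each culture's mean as deposited and the 2-fold count over genes measured in both orientations, with and without array 1. Calls were 83 (60 higher) without centring, 67 (51 and 16) with quantile normalization, 43 (43 and 0) over genes with values on at least 3 arrays, 474 (328 and 146) and 331 (236 and 95) under each pairing alone, 116 (10 lower) with 4 arrays as replicates, 501 (335 and 166) with a dye term, 1140 (680 and 460) on the Cy3 arrays, 84 lower on the Cy5 arrays, 114 (99 and 15) with robust shrinkage, 577 (368 and 209) at adjusted p under 0.1 and 0 (0 and 0) under 0.01. Each pairing alone gave more calls because the main result took the larger p of both. On arrays of one orientation the orientation effect does not cancel and can enter the calls. With 4 arrays as replicates, the dye swaps of a culture count as replicates. How far this moved the counts, and the cause for the rest, was not tested. Leaving out 1 array gave 43 to 120 calls, 43 to 113 higher and 0 to 7 lower. The 2-fold count (60 higher, 0 lower) was 129 and 32 on the Cy3 arrays, had 12 lower on the Cy5 arrays, 1 lower without centring, 3 with quantile normalization, 2 with at least 3 arrays, 9 over genes measured in both orientations (3 of them 2-fold over the arrays other than array 1) and 58 to 80 higher and 0 to 3 lower with 1 array left out. It was 163 and 36 at 1.5-fold and 20 higher at 3-fold. Of the lists (9 higher, 1 lower), 5 and 2 were called on the Cy5 arrays, 11 and 1 on the Cy3 arrays, 5 higher under 0.01 and 0 and 0 with an estimated correlation, on culture means or on 4 arrays. Fry, another set test, called 8 higher and 1 lower on 4 arrays with an orientation term. It ended the calls of osmotic stress (adjusted p = 0.125), trehalose and glycogen (0.0824) and calcineurin targets (0.0616). It added chitin synthesis (0.00755) and polarity (0.00906). In camera on the Cy5 arrays, the call was lost by integrity pathway components (0.073), trehalose and glycogen (0.279), calcineurin targets (0.24) and daughter cell separation (0.103). With 1 array left out, 7 to 11 lists were called higher and 1 lower. Heat shock chaperones turned to a called fall on the Cy5 arrays (adjusted p = 0.016) and were called higher on the Cy3 arrays (0.0225). Ribosome biogenesis was not called on the Cy3 arrays (0.704); the list called lower there was that of genes of another mating type and of meiosis (0.0468), with polarity (0.0232) added to the higher ones. Of 51 named genes past the threshold, none changed sign in a called value; 30 lost the call with at least 3 arrays, 24 with quantile normalization, 19 without centring, 16 with robust shrinkage and 19 to 30 with 1 array left out. Fits that leave out 1 array take its partner alone as the culture's value, and the lone array is assumed to vary like a culture mean. The orientation effect does not cancel in that culture, so lost calls do not measure dependence on the array alone. The median of spots per gene was not run, since each gene had 1 spot, nor robust shrinkage for the lists, as camera does not take it. Each ratio already compares treated with untreated RNA on the same array. No pairing between groups of arrays applied, because all arrays belong to 1 group. Signal over background is not known here.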

Other observations

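Of the 184 genes called, 125 belonged to none of the lists (103 higher, 22 lower), as did 20 of the 36 genes called with each array left out in turn. The 4 groups described here were put together after their leading genes had been seen, so they are described by counts and values and were given no test as groups. Of 16 measured genes of purine synthesis and its one-carbon supply, 4 rose, 0 fell and 15 had a mean above 0, with group medians of 0.467, 0.43, 1.02 and 0.749 on arrays 1 to 4. ADE17, which encodes an enzyme of the last steps of inosine monophosphate synthesis, rose by 1.68 ± 0.27 (adjusted p = 0.0381). The glycine cleavage genes GCV2 and GCV3 rose by 1.12 and 0.66, and the serine hydroxymethyltransferase gene SHM2 by 1.01. ADE1 at 0.84, MTD1 at 0.81 and GCV1 at 0.89 did not pass (adjusted p = 0.0596, 0.0596 and 0.0511), and SHM1, of the mitochondrial enzyme, had -0.05. In purine salvage and GMP synthesis, 2 of 8 genes fell and 7 had a mean below 0 (median -0.37). AAH1, the adenine deaminase gene, fell by 0.91 ± 0.11 (adjusted p = 0.0397) and IMD4 by 0.52.

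Of 11 genes of autophagy and vacuolar proteases, 3 rose, namely ATG8 by 1.23, PRB1 by 1.06 and ATG42 by 0.52, and all 11 had a mean above 0. Of 6 zinc genes, the transporter genes ZRT1 and ZRT2 fell by 0.52 and 0.59, but the group's medians were -0.816 and -0.997 on arrays 1 and 3 and 0.129 and 0.0815 on arrays 2 and 4. Of the 11 called genes in these 4 groups, 1 (GCV2) was called with each array left out in turn, and the others lost their call in at least 1 of these fits. Genes outside the lists and groups that were called in all of these fits include NCE103, the carbonic anhydrase gene, at 1.47, RCR1, a gene linked to chitin deposition in the wall, at 1.16, PUN1 at 1.66 and STF2 at 1.40. Of the genes measured on fewer arrays, ALD4, which encodes a mitochondrial aldehyde dehydrogenase, had 2.02 and 1.34 on arrays 3 and 4, and PTP2, a phosphatase gene of the integrity and HOG pathways, had 1.00, 0.73 and 0.65 on arrays 1, 3 and 4. Among the falls in such genes, YCR099C had -1.90 and -0.12 on arrays 3 and 4, YRB30 -1.08, -3.42 and -0.17 on arrays 1, 3 and 4, and PRM7 -0.88, -1.90 and -0.62 on arrays 2, 3 and 4. All 5 genes were chosen after their values had been seen.

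Arrays of one dye orientation resembled each other more than arrays of opposite orientation, with r of 0.615 and 0.778 against 0.146 to 0.216 across genes. Of the tests below, all but the one on glutamine- or asparagine-rich proteins were chosen after the result had been seen. That one was written down before its result, but after top genes had been seen. These genes were left out of its list, while the choice of the protein class may still rest on the same data. Ratios left in their dye direction would put the cell wall integrity output list in the part of the values that turns with the orientation. Its median there was 0.0705, inside the central 95% of 10000 random lists (-0.144 to 0.14), while its median in the mean over arrays was 1.39, outside the range of -0.108 to 0.169, which argues against it. A dye effect set by the sequence of the cDNA, labelled through dUTP, was tested on 38 genes of glutamine- or asparagine-rich proteins, and their median in the orientation part was -0.171, below the central 95% of length-matched lists (-0.136 to 0.0485), which is consistent with such an effect for part of the pattern, although random lists take genes as unrelated. A hybridisation batch shared by arrays of one orientation cannot be told apart from the dye, since 0 arrays have a batch in the labels or files.

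Rises outnumbered falls among the calls. Centring of the arrays on the median may have added to this, but with values as deposited rises still made up 72.3% of 83 calls. Genes are not independent, so the spread was taken between cultures. Among genes at least 2-fold in a culture's mean, as deposited, rises made up 79.3% (SE 6.02, n = 2 cultures) with arrays 1 and 2 in one culture and 89.8% (SE 0.458) with arrays 1 and 4 in one. This argues against centring as the whole cause for changes of that size, although an SE from 2 cultures is itself imprecise. It does not speak for the smaller changes, which made up most of the calls. Blank spots could have removed genes that fell. Among 627 genes measured in both orientations but blank on some array, 9 were lower and 2 higher at least 2-fold with one sign (exact binomial test, two-sided p = 0.0654, which takes genes as independent), but 6 of the 9 falls, among them SKN1, BUD27 and SAN1, were no longer 2-fold in the mean over the arrays other than array 1, and so was 1 of the 2 rises. With 3 falls and 1 rise left, the 2-fold count does not decide. At any size, however, most of the 627 genes had a mean over both orientations below 0. Of the 3740 genes tested, 16.6% were above 0 on all 4 arrays and 10.9% below. The medians used for centring included partly blank genes. Leaving these genes out may thus have added to the excess of rises, and this explanation stays open. No biological explanation was tested for either pattern, as the design has 1 comparison.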
